A study of Mus musculus with 36 samples.

How the data were processed

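The series measured RNA and chromatin accessibility in primary cortical neurons from mouse embryos at embryonic day 16.5, kept in culture for 7 days. The neurons came from wild-type (WT) embryos or from embryos lacking Actl6b (KO), the neuron-specific actin-related subunit of the BAF chromatin remodelling complex. The 24 RNA-seq libraries form 5 groups and the 12 ATAC-seq libraries form 2 groups. Resting cultures had 2 h in TTX and APV, which block sodium channels and NMDA receptors and so silence activity. WT cultures were also depolarised with KCl for 1 h or 6 h, and a further WT control group had 7 h in TTX and APV. The KCl cultures had TTX and APV too, 2 h for 1 h of KCl and 7 h for 6 h of KCl. Each KCl group and its control thus had the blockers for the same time and differed in KCl. Each library's title carries a code, read here as that of its culture. All 12 codes at rest, 5 WT and 7 KO, occur in both assays. The series describes the cultures as separate biological replicates.

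The RNA-seq files list 115270 transcripts, each with its estimated count and effective length, per the file headers. The deposited estimated counts need not be whole numbers. The submitters' processing notes name Trim Galore, kallisto 0.44.0, DESeq2, Bowtie2, MACS2 and bedtools and the builds mm9 and mm10, without saying which step each belongs to. The RNA libraries were made from total RNA with a stranded kit, per the labels' protocols. The deposited ATAC-seq files give whole-number read counts in 76570 regions that are the same in every library. How the regions were chosen and whether reads were shifted to the insertion site of the transposase is not given in the sources used here. The last region on chromosome 1 ends at 197068294, beyond the mm10 end of that chromosome at 195471971, and 9 chromosomes hold a region beyond their mm10 end. The coordinates are therefore read as mm9.

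The files used here do not pair the transcript identifiers with genes, and no identifier matched the tables of gene names used here. The tests were planned per gene. Counts could not be summed per gene, so every RNA test was made per transcript, on estimated counts rounded to whole numbers. The level of Actl6b was not analysed here, so the genotype labels were not checked against it. The 22 gene lists fixed beforehand, early response genes included, were not analysed here either. A transcript's count also depends on how kallisto assigned reads among transcripts of the same gene, so a change can be a change in assignment between isoforms. Transcription start sites, GC content and AP-1 motifs in the ATAC-seq regions were not analysed here, since no mm9 sequence or annotation was used.

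Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F-test with robust estimation, TMM scaling and filterByExpr by group. Adjusted p-values are Benjamini-Hochberg values over all features tested in a comparison, with a threshold of 0.05. Each fit held only the groups compared. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. The comparisons were KO against WT at rest in both assays, 1 h KCl against rest, 6 h KCl against 7 h TTX and APV, 7 h against 2 h of TTX and APV, and the difference between the 6 h and the 1 h KCl responses (an interaction contrast over the 4 WT groups). Transcripts with an adjusted p under 0.05 and a log2 fold change of at least 1 were called induced, and those at the opposite limit repressed. Sets of induced transcripts were tested in KO against WT with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. A score per culture was the mean log2 CPM of a set, with a prior count of 2, minus that of all tested transcripts, and was compared by a two-sided exact permutation test over all 792 splits of the 12 cultures.

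The main designs, the list of alternatives and the rule for named items were set before the data were examined. The rule took the features with the largest change in each direction among those past the threshold, with a mean of at least 1 CPM and no overlap between the log2 CPM values of the groups. It gave 10 regions per direction. Of transcripts only the first 2 per direction in KO against WT are printed, because they have no gene name here. The parts of the rule that need gene symbols could not be applied. Alternatives covered DESeq2 1.42.0, other scalings, no filter, an effective length offset, all RNA libraries in one fit, the first number of the culture code as a covariate, the culture code as a replicate block and leaving out each library. Embryo sex was taken from counts in the 3 regions on chromosome Y instead of from named transcripts, a choice made after seeing the data.

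The WT groups share codes, and the labels do not say what a code marks. The WT RNA-seq libraries carry 5 codes in all, the number of WT biological replicates that the series states, so a shared code was read as the same replicate and fits with the code as a block are given as paired alternatives. The data bear on this reading only weakly, as all correlations were small. Deviations of same-code libraries from their group means correlated from 0.00253 to 0.0737 for 1 h KCl, where different codes gave -0.0916 to 0.0799. For 6 h KCl the ranges were 0.0236 to 0.0713 and -0.0478 to 0.0109, and for the controls at 7 h and 2 h -0.0336 to 0.0448 and -0.0333 to 0.0713. Only for 6 h KCl did every same-code value lie above every different-code one. KO and WT share no code, so their comparison has no pairs.

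Total estimated counts ran from 5873350 to 8015060 in the resting and 1 h KCl libraries and from 3569520 to 4051920 in the libraries of the 6 h experiment. ATAC-seq totals in regions ran from 4679644 to 7262297. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom among 81 pairs was 3.58. On simulated counts with 100 features changed at each fold size, a log2 change of 2 was recovered for 54% of transcripts in KO against WT, 55% for 1 h KCl, 28% for 6 h KCl, 44% for 7 h against 2 h, 27% for the interaction and 87% of ATAC-seq regions. At a log2 change of 1 the shares were 25%, 19%, 5%, 14%, 4% and 49%. Fewer features were changed in the simulations than were called in the data, which makes the adjusted p stricter there. The shares therefore do not measure the power of the real comparisons. Floors for counts of 0 are 3 counts over all libraries of a group and cover counting error only.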

Results

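Neurons of 5 WT and 7 KO cultures were profiled at rest by RNA-seq and ATAC-seq. Further WT RNA-seq libraries came from 5 cultures after 1 h of KCl, 4 after 7 h of TTX and APV and 3 after 6 h of KCl. Resting WT libraries held 5873350 to 7578710 estimated counts and resting KO libraries 6135380 to 7480900. The 1 h KCl libraries held 6902980 to 8015060. The 7 h TTX/APV libraries, with 3569520 to 4020980, and the 6 h KCl libraries, with 3627450 to 4051920, were shallower. ATAC-seq libraries held 4679644 to 7262297 counts in regions in WT and 5296643 to 7040224 in KO. The first principal component, with 27.6% of the variance of the RNA-seq libraries, set the 7 h TTX/APV and 6 h KCl libraries (172 to 199) apart from all others (-108 to -56.9).

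**Figure D1:**
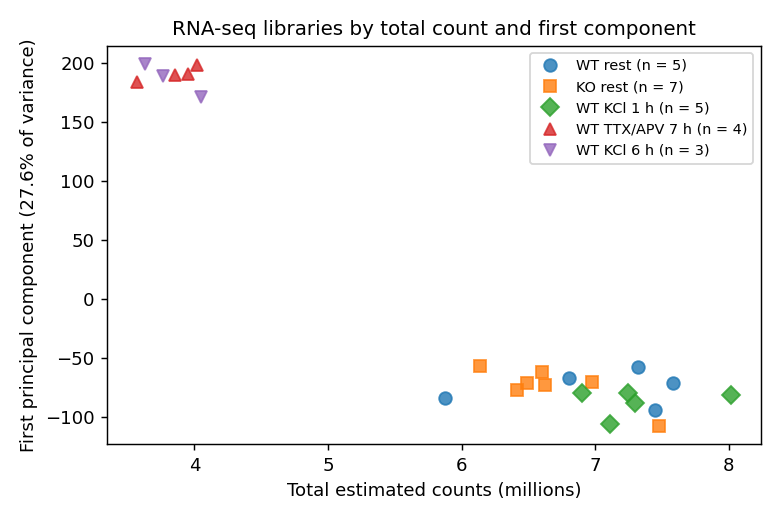
Total estimated counts (x axis, mega-counts) against the first principal component of log2 CPM (y axis) for the 24 RNA-seq libraries, 1 point each, by group. The libraries of the 6 h experiment lie at 3.57 to 4.05 on the x axis and at 172 to 199 on the component, and all others at negative values.

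The first comparison asked which transcripts differ between KO and WT neurons at rest. Of 32904 transcripts tested, 429 were higher and 537 lower in KO. Most changes were small: 156 of the higher and 92 of the lower transcripts changed at least 2-fold, and the median log2 fold change was 0.78 among the higher and -0.60 among the lower ones. The transcript with the smallest adjusted p (2.48e-07, edgeR), singled out after its values were seen, is 1592 bases long and fell from 59.99 ± 6.43 CPM (SD, n = 5) in WT to 6.70 ± 1.21 CPM (SD, n = 7) in KO, a log2 fold change of -3.17 (SE 0.129). Its level was 55.8 ± 3.51 CPM after 1 h of KCl (SD, n = 5) and 20.1 ± 1.36 CPM after 7 h of TTX and APV (SD, n = 4), and 19.97 ± 0.848 CPM after 6 h of KCl (SD, n = 3).

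By the rule for named items, the largest changes were transcripts listed at 0 in every library of one genotype. ENSMUST00000113882.7 was at 0 in all 5 WT libraries and at 7.21 ± 3.57 CPM in KO (SD, n = 7), at least 77.8-fold higher against a floor of 0.0927 CPM over the group (edgeR adjusted p = 0.00371). In the other WT groups it was at 4.55 ± 5.54 CPM after 1 h of KCl (SD, n = 5), at 8.82 ± 6.27 CPM after 6 h of KCl (SD, n = 3) and at 0.473 ± 0.945 CPM after 7 h of TTX and APV (SD, n = 4). ENSMUST00000177162.7 was at 0 in WT and at 5.98 ± 3.76 CPM in KO (SD, n = 7), at least 64.6-fold higher (edgeR adjusted p = 0.00898), and at 0.795 ± 1.78 CPM after 1 h of KCl (SD, n = 5) and 0 in both groups of the 6 h experiment. In the other direction, ENSMUST00000134465.7 was at 8.13 ± 5.40 CPM in WT (SD, n = 5) and at 0 in KO, at least 116-fold lower against a floor of 0.0704 CPM (edgeR adjusted p = 0.00686), and it was at 0 in all 1 h KCl libraries and all 7 h TTX/APV libraries as well, and at 0.480 ± 0.831 CPM after 6 h of KCl (SD, n = 3). ENSMUST00000209490.1 was at 2.56 ± 0.656 CPM in WT (SD, n = 5) and at 0 in KO, at least 36.3-fold lower (edgeR adjusted p = 0.00534). It was at 1.38 ± 2.28 CPM after 1 h of KCl (SD, n = 5), 0.155 ± 0.309 CPM after 7 h of TTX and APV (SD, n = 4) and 0.480 ± 0.831 CPM after 6 h of KCl (SD, n = 3). A listed 0 can reflect the assignment of reads among isoforms.

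In 796 of the 966 changed transcripts the log2 CPM values of the 2 genotypes did not overlap. Over all tested transcripts this held for 3.72%, where chance gives 0.253%. The number of changed transcripts fell by more than 1.5 times, to 511, 517, 439 and 474, without WT library 3-4, 3-7, 4-2 or 4-4, and to 581 and 530 without KO library 3-2 or 4-7. It was 456 without a filter on low counts and 2109 by DESeq2.

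Depolarisation for 1 h was compared with rest to find the early response of WT neurons to activity. Of 31673 transcripts tested, 806 rose and 632 fell, and 505 rose and 450 fell at least 2-fold. Large rises outnumbered large falls: 104 transcripts rose and 28 fell by a log2 fold change of at least 3. With the culture code as a block 436 rose and 220 fell, 656 in all. DESeq2 called 2336 transcripts and edgeR with all RNA libraries in one fit 2294.

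After 6 h of KCl, set against 7 h of TTX and APV without KCl, 2808 of 33196 transcripts rose and 2283 fell, 1607 and 1593 of them at least 2-fold. With the culture code as a block, which leaves 2 residual degrees of freedom, 610 rose and 202 fell, 812 in all, and DESeq2 called 7913. The total of 5091 dropped to 3376 without the 7 h TTX/APV library 3-4 and to 3054 and 3055 without the 6 h KCl library 3-7 or 4-2. When libraries were scaled by total counts alone, the median log2 fold change of all transcripts moved from -0.03 to -0.23 and the share of higher calls from 55.2% to 36.4%, so the balance of rises and falls depends on the scaling.

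The responses at the 2 times differed in 4052 of 46790 transcripts by the interaction contrast, 2170 with a higher and 1882 with a lower response at 6 h. The sets induced at either time were chosen for their fold change in libraries that also enter this contrast, so the choice by itself favours a larger response at the time used for it, in the counts and medians that follow. Of the 505 transcripts induced at 1 h, 155 had a lower response at 6 h and 15 a higher one. Of the 423 tested at 6 h, 167 were called higher there as well (edgeR), and the median log2 fold change of the set was 1.78 at 1 h and 0.81 at 6 h. Of the 1607 transcripts induced at 6 h, 892 had a higher response than at 1 h and 21 a lower one, and their median log2 fold change was 0.19 at 1 h and 1.54 at 6 h. With the culture code as a block 375 in place of 892 had a higher response at 6 h, and scaled by total counts 578 did. That scaling moved the median of all transcripts to -0.18 and the share of interaction calls with a higher response at 6 h from 53.6% to 35.9%.

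The 2 silenced controls were compared because each KCl group has its own. Between 7 h and 2 h of TTX and APV, 19402 of 35933 transcripts (54.0%) differed, 10161 higher and 9241 lower at 7 h, with 8630 and 5970 changed at least 2-fold. All 7 h libraries, and none at 2 h, belong to the set with lower totals and a separate position on the first component. Scaling by total counts moved the median log2 fold change of all transcripts from -0.03 to 0.37 and the share of higher calls from 52.4% to 68.5%. Of 2588 transcripts higher after 6 h of KCl, 1406 were lower at 7 h than at 2 h, against 674 for independent lists. Another 412 were higher, against 809. Of 2279 lower after 6 h of KCl, 1145 were higher at 7 h, against 712, and 373 lower, against 594. The shared 7 h libraries by themselves favour this. A call at 6 h of KCl is a difference from the 7 h control and need not be one from 2 h.

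Transcripts that respond to KCl in WT were then followed in resting KO neurons. Of 1354 tested transcripts from the 6 h-induced set, 950 (70.2%) had a positive log2 fold change in KO, with a median of 0.17. Among them 71 were called higher and 7 lower, and adjusted over the list alone 104 and 14; the list was chosen on WT cultures with the same codes. The set ranked above other transcripts (camera p = 1.52e-08, adjusted 1.06e-07 over 9 sets), but not with an estimated correlation (p = 0.0563 with an estimated correlation). The score per culture was 1.17 ± 0.115 in KO (SD, n = 7) and 0.946 ± 0.124 in WT (SD, n = 5), a difference of 0.22 (two-sided exact permutation p = 0.0126, adjusted 0.0168 over 4 sets). All 7 KO cultures lay above the WT mean and 4 above every WT culture. Among cultures whose code starts with 3 the difference was 0.38 (3 KO, 2 WT) and among those starting with 4 it was 0.19 (2 KO, 3 WT). With the set defined in cultures 3-7, 4-2 and 4-4 and KO compared with WT cultures 3-4 and 4-3 alone, the median over 1166 transcripts was 0.11.

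Calls overlapped by direction. Of the transcripts tested in both comparisons, 112 were higher both in KO and after 6 h of KCl, where independent lists would share 35.2, and 92 were lower in both, against 39.5. Within 20 classes of mean CPM, independent lists would share 58.9 and 40.9, ratios of 1.90 (SD 0.113) and 2.25 (SD 0.147) in place of 3.19 and 2.33; the value for the lower transcripts was added after the results were seen. The classes are of mean CPM in the resting libraries, and the SDs treat transcripts as independent draws. In opposite directions 24 and 50 were shared, against 28.7 and 48.3. The shared counts were 34 and 20 with the culture code as a block in the KCl comparison, 329 and 247 by DESeq2 and 53 and 30 without a filter, and with all RNA libraries in one fit 206 were higher in both. The 112 became 58, 63, 59 and 52 without WT library 3-4, 3-7, 4-2 or 4-4 and 68, 74 and 66 without KO library 3-2, 3-3 or 4-7. The 92 became 52, 48, 42, 43, 54, 57 and 51 without the same libraries in that order, and 61 without the 6 h KCl library 4-2.

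The 1 h-induced set was defined with the same resting WT libraries as the KO comparison, so its shift is not independent of that definition. This covers its score per culture too, with a KO minus WT difference of 0.232 (two-sided exact permutation p = 0.0126). Of 361 tested transcripts, 246 had a positive log2 fold change in KO, with a median of 0.17; 9 were called higher and 1 lower, also when adjusted over the list alone (camera p = 2.58e-05, adjusted 4.64e-05; p = 0.112 with an estimated correlation). Simulated libraries with the KCl effect kept and KO unchanged gave a mean median of 0.15 and a highest of 0.18 over 10 simulations, so the shared controls alone can give the observed size. With the controls split by culture, so that different WT cultures defined the set and were compared with KO, the set median ranged from 0.11 to 1.46 over those of 20 splits that gave a set, with 0.23 in their median. The sets held 53.5 transcripts in the median over all 20 splits, and some splits gave none, so this pooled value is unstable. Where the larger part of the WT cultures defined the set, it held 100 to 211 transcripts, with medians of 0.11 to 0.28. Where the smaller part did, it held at most 7, and the 1.46 came from a set of 2. All splits reuse the same libraries and are not independent of each other. The correlation of log2 fold changes was 0.263 as observed, 0.365 in simulations with the KCl effect kept, 0.552 in those without any effect and 0.00544 in the median of the split controls. The covariance was 0.0793, 0.117, 0.114 and 0.00437 in the same order.

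Of the 6 h-repressed transcripts tested in KO, 43 were called lower and 14 higher, and adjusted over the list alone 54 and 18. The median log2 fold change was -0.08 (camera p = 0.0300, or p = 0.183 with an estimated correlation). The score per culture was -0.0981 ± 0.0697 in KO (SD, n = 7) and -0.00893 ± 0.0535 in WT (SD, n = 5), with a two-sided exact permutation p = 0.0429. Lower calls also outnumbered higher ones over all transcripts, 537 to 429. The 1 h-repressed set was defined with the resting WT libraries of the KO comparison, and no simulated value was made for it. Of its 450 transcripts 6 were called lower and 1 higher, and adjusted over the list alone 1 and 0, with edgeR (camera p = 0.0260, or p = 0.384 with an estimated correlation). The KO minus WT difference in its score per culture was -0.121 (two-sided exact permutation p = 0.0101), which is not independent of the shared libraries. Among all transcripts tested in both, 10 were lower in KO and after 1 h of KCl, where independent lists would share 11.2. Another 16 were higher in both, against 8.63. In opposite directions 2 were higher in KO and lower after KCl, against 8.24, and 8 lower in KO and higher after KCl, against 11.7. The resting WT libraries enter both comparisons, so these overlaps are not independent of them. KO library 1-1 stood apart in the score of this set, at -0.71 against -0.47 in the nearest other.

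**Figure D2:**
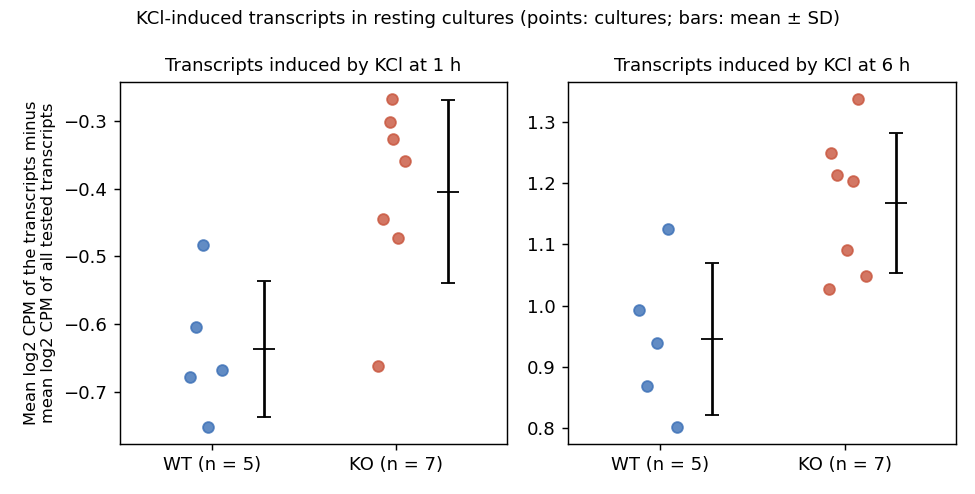
Score of the transcripts induced by KCl at 1 h and at 6 h (y axis, mean log2 CPM of the set minus that of all tested transcripts) in resting WT and KO cultures, 1 point per culture, with bars for mean ± SD. For the 6 h set the KO mean is 1.17 and the WT mean 0.946.

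ATAC-seq under the same 12 culture codes asked where accessibility differs with genotype. Of 73346 regions tested, 385 were more and 209 less accessible in KO (edgeR), and 246 and 49 of them changed at least 2-fold. The strongest gain by the rule was on chromosome 2 at 10934793 to 10935362 (mm9), from 0.900 ± 0.597 CPM in WT (SD, n = 5) to 4.62 ± 3.26 CPM in KO (SD, n = 7), a log2 fold change of 2.37 (SE 0.511, edgeR adjusted p = 0.0152). KO library 3-3 stood apart there, at 11.5 CPM, and the call was lost without it (edgeR adjusted p = 0.0919) and without WT library 3-7 (0.0535) or 4-4 (0.0586); over all alternatives the adjusted p ran down to 0.00288. A region on chromosome 5 at 86615944 to 86616711 rose from 3.17 ± 1.67 to 13.3 ± 3.75 CPM (SD, n = 5 and 7; log2 fold change 2.02, SE 0.273, edgeR adjusted p = 2.35e-05), and one on chromosome 9 at 14400839 to 14401313 from 2.97 ± 1.32 to 12.2 ± 5.32 CPM (SD, n = 5 and 7; log2 fold change 2.02, SE 0.301, edgeR adjusted p = 1.77e-04). Of the regions that closed, the one with the largest change, on chromosome 7 at 74830467 to 74831109, fell from 4.70 ± 1.53 to 1.37 ± 0.491 CPM (SD, n = 5 and 7; log2 fold change -1.77, SE 0.411, edgeR adjusted p = 0.0231). That call was lost without WT library 3-4 (edgeR adjusted p = 0.122) or 4-4 (0.0845), without KO library 3-3 (0.0549) and with thinned counts (0.0700); over all alternatives the adjusted p ran from 0.00193 to 0.122. A region on chromosome 11 at 36802464 to 36803201 fell from 13.9 ± 3.42 to 5.47 ± 1.34 CPM (SD, n = 5 and 7; log2 fold change -1.35, SE 0.230, edgeR adjusted p = 0.00126). The region with the smallest adjusted p, singled out after its values were seen, lies on chromosome X at 103381661 to 103383426 and had a log2 fold change of 1.38 (SE 0.114, edgeR adjusted p = 4.00e-12). Being outside the rule, it was not followed through the alternatives, embryo sex and single libraries included. Counts on chromosome Y were present in 3 of the 5 WT and 4 of the 7 KO libraries, so both genotypes held both sexes by this measure. The 10 named gains had log2 fold changes of 1.85 to 2.37 and the 10 named losses -1.77 to -1.24. Which genes lie near these regions was not analysed here.

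Gains and losses lay at different mean levels over all libraries, a difference that was not tested. Regions that lost accessibility had a median of 15.1 CPM and a median width of 1060 bp, those that gained it 9.20 CPM and 818 bp, and unchanged regions 7.49 CPM and 742 bp. Among the 18337 regions with the lowest levels 51 rose and 5 fell, and among the 18337 with the highest 83 rose and 106 fell. In 289 of the 594 changed regions the 2 genotypes did not overlap. Over all tested regions this held for 1.32%, where chance gives 0.253%. The count depended on single libraries: it was 140, 221, 280 and 95 without WT library 3-4, 3-7, 4-2 or 4-4, 212, 207, 241 and 353 without KO library 3-2, 3-3, 4-7 or 4-8, and rose to 1582 without WT library 4-3 and to 1395 without KO library 2-3. With the first number of the culture code as a covariate it was 1466, at an adjusted p under 0.01 it was 84 and by DESeq2 it was 1250. KO libraries 1-1 and 2-3 are each alone in their first number. The covariate fit therefore takes the genotype difference from the other libraries only. The first component of the ATAC-seq libraries, with 23.2% of the variance, set WT library 4-3 and KO libraries 1-1, 3-2, 3-3, 4-7 and 4-8 (14.7 to 106) apart from KO libraries 2-3 and 3-5 and the other WT libraries (-83.9 to -23.9).

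**Figure D3:**
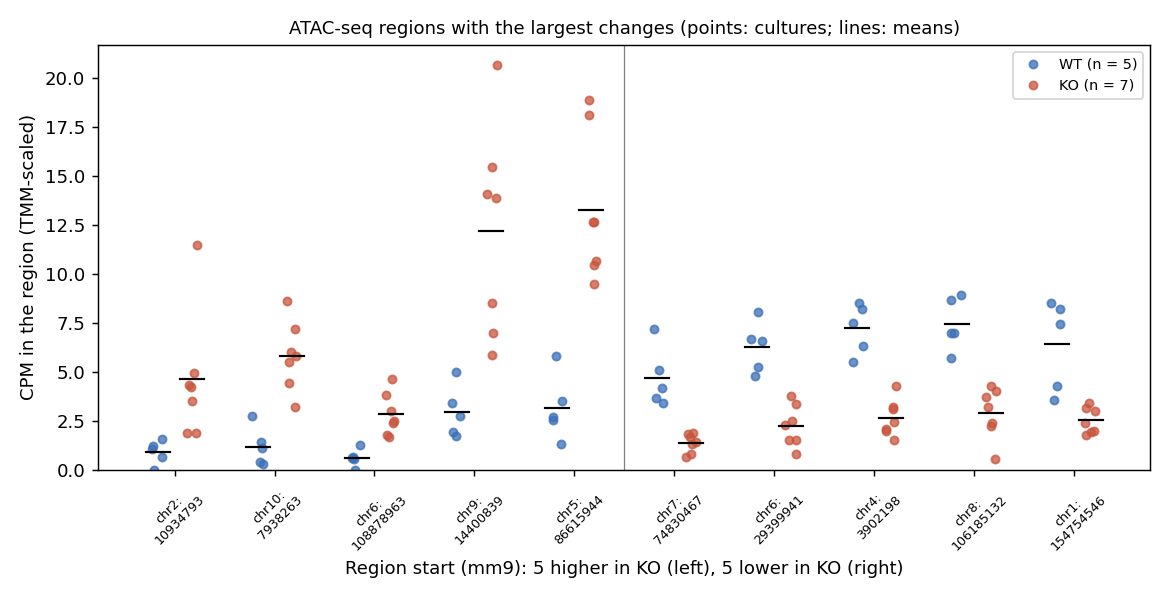
TMM-scaled CPM (y axis) in 10 ATAC-seq regions (x axis, mm9 start) by culture, with lines for group means: the 5 named regions with the largest gain in KO on the left and the 5 with the largest loss on the right. No WT culture overlaps a KO culture in log2 CPM within a region.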

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

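The thinned counts and the share of counts in the most accessible regions as a covariate were chosen only after the main results were seen, the ratio of log2 fold changes with and without that covariate after its counts of calls were seen too, and so was a margin of 2 standard errors on the bounds for the length trend and the shares of gains; the other tests of explanations were written down before their results were seen.

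The response to KCl differed between 6 h and 1 h in 4052 transcripts by the interaction contrast. Libraries far from the rest of their group were found in 5 of 62 groups of values tested, where chance gives about 1 in 20. The 7 h TTX/APV library 3-7 had 59981 detected transcripts against 61496 in the nearest other (gap over range 0.936). KO library 1-1 had a score of -0.71 for the 1 h-repressed transcripts against -0.47 in the nearest other (0.792). WT library 3-7 had 16.4 CPM in the region on chromosome 18 at 13083440 to 13084051 against 8.35 in the nearest other (0.844). KO library 3-3 had 11.5 CPM against 4.96 in the region on chromosome 2 at 10934793 (0.680) and 13.4 CPM against 7.94 in the one on chromosome 1 at 45549041 to 45549554 (0.683).

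Transcripts induced by 6 h of KCl lay higher in KO at rest. Abundant transcripts are called more easily in any comparison. Within 20 classes of mean CPM in the resting libraries the overlap of both lists was 1.90 times that of independent lists (SD 0.113), against 3.19 without classes. Abundance at rest thus accounts for a part of it but not for the whole. Within classes of transcript length the ratio was 2.79 (SD 0.147), which argues against length as the whole cause. Both SDs treat transcripts as independent draws, so they can be too small where transcripts vary together. The exact permutation p of the score per culture, 0.0126, argues against variation between cultures, but the camera test with an estimated correlation gave p = 0.0563 and 1 mixed split of the cultures gave a larger median. Loss of Actl6b may raise these transcripts at rest, a hypothesis found and tested on the same libraries.

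Of the transcripts tested, 54.0% differed between 7 h and 2 h of TTX and APV. With all libraries thinned to the lowest total, 16846 transcripts were called, against 19402, so depth is not the whole cause. Spearman's rho between log2 fold change and length across the called transcripts was 0.0969 (SE 0.00718), within its error of the bound of 0.1, and leaves a small length trend open. The log2 fold change from 1 h to 6 h of KCl had a slope of 0.777 on that of the silenced controls, and 92.0% of the called transcripts had the same sign in both. Hours of TTX and APV and a separate preparation of the 7 libraries of the 6 h experiment cannot be told apart, because no library of that set was taken at the earlier times.

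More ATAC-seq regions gained than lost accessibility in KO, 64.8% of the calls. With every library thinned to the lowest total, 65.1% (SE 2.12) of 507 calls were gains, so the depth of counts within the given regions is not the cause. How the regions were chosen is not known, so an effect of depth on that choice was not tested. With the share of counts in the most accessible regions as a covariate, 396 gains and 255 losses were called, against 385 and 209 without it. The gains kept a median of 0.921 of their log2 fold change (lower quartile 0.849) and 278 of the 385 stayed called, which argues against signal over background as the source of the gains as a whole. The share of gains fell to 60.8% (SE 1.91), within its error of the bound of 60%, but because losses rose, so it is no evidence that background produced gains, and whether background hid losses stays open.

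Other splits of the same libraries were refitted for each count. For KO against WT transcripts the real split gave 966 calls and the highest of the others 2 (1 of 100 splits as large), for 1 h KCl 1438 and 3 (1 of 100), for 6 h KCl 5091 and 2 (1 of 35) and for 7 h against 2 h 19402 and 8179 (1 of 100), so chance can be excluded for these when splits are drawn without regard to the codes. The split with 8179 calls set 4 of the 5 resting libraries against the remaining one and all 7 h libraries, and so follows the times. The splits that part as many same-code pairs are too few for a share under 0.05. Among them the real split gave 1438 calls and the highest other 1 for 1 h KCl (16 splits), 5091 and 0 for 6 h KCl (8 splits, edgeR) and 19402 and 3749 for the controls (16 splits).

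For the interaction 2 of 100 splits were as large, 4052 calls in the real one and 8884 in the other. That split kept the KCl groups and mixed the silenced controls, so the difference between those controls entered the contrast. For the 1 h-induced set 4 of 100 splits of the KO comparison gave as large a median, 0.17 in the real one and 0.18 in the highest other, and for the 6 h-induced set 2 of 100, 0.17 in both. For ATAC-seq 3 of 100 splits were as large, with 594 calls in the real one and 927 in the highest other. For the 6 h-induced set and for ATAC-seq the share is under 0.05. It comes from 100 of 792 possible splits in each, and is too imprecise to exclude chance. Over all 792 splits, the two-sided exact permutation test of the score of the 6 h-induced set gave p = 0.0126. The interaction splits cannot decide, because they mix libraries of the 2 times. In the silenced controls alone 54.0% of transcripts differed between the times, so such splits do not show what chance gives. For the 1 h-induced set the splits decide nothing, because it was defined with the real resting WT libraries and was not redefined for each split. Both ATAC-seq splits with more calls put WT library 4-3 with KO libraries 1-1, 3-2, 3-3, 4-7 and 4-8, the libraries on one side of the first ATAC-seq component. This points to a structure of these samples besides genotype. These libraries held 40.5% to 43.5% of their counts in the most accessible regions, and all others 43.8% to 46.9%. The structure thus goes with signal over background, but whether that made the calls in these splits was not tested. With the first code number as a covariate 1466 regions were called.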

How the results depend on the processing

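Embryo sex, thinned counts, the share of counts in the most accessible regions and fits within a first code number were chosen after seeing the data; all other alternatives were planned. DESeq2 called more, 2109 transcripts in KO against WT, 2336 at 1 h, 7913 at 6 h and 1250 regions; 942, 1437, 5087 and 592 of the edgeR calls were among them in the same direction. Without a filter 456 transcripts changed in KO, and with all RNA libraries in one fit 2294 changed at 1 h. The culture code as a block gave 656 at 1 h and 812 at 6 h, with fewer residual degrees of freedom, and moved no other count of calls of a comparison by over 1.5 times. For ATAC-seq an adjusted p under 0.01 left 84 regions, a stricter threshold by construction. The first code number gave 1466, in a fit where KO libraries 1-1 and 2-3 carry no weight in the genotype difference. Apart from the stricter threshold the cause was not tested. The KCl-induced sets lost their camera call with an estimated correlation (median 0.17 and p = 0.112 at 1 h, median 0.17 and p = 0.0563 at 6 h) and under no other alternative run. Leaving out 1 library gave 439 to 967 transcripts in KO, 1014 to 1285 at 1 h, 3054 to 4044 at 6 h, 17413 to 18597 for 7 h against 2 h, 3253 to 4055 for the interaction, 95 to 1582 regions, and set medians of 0.15 to 0.25 (1 h) and 0.14 to 0.21 (6 h). The 4 named transcripts kept their call in all 82 alternative fits; for the named regions it was lost in 80 of 399 fits and no direction reversed. Not run were GC correction, distances to genes and AP-1 alternatives, the alternatives of the early response list, and sex from named transcripts. In the 6 h comparison, with the lowest depth and the fewest libraries, 28% of simulated log2 changes of 2 were recovered. That simulation changed fewer transcripts than were called in the data, so this share is not the power of the real comparison. The limits of depth and of library number were not separated.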

Other observations

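The overlaps of changed transcripts between comparisons were looked at after the main results were seen, while the test of neighbouring regions was written down before its result. The KCl responses at 1 h and 6 h, which share no library, overlapped by direction: 309 transcripts rose at both, against 68.9 for independent lists, and 177 fell at both, against 45.9. Opposite directions were rarer than independent lists would give, with 11 and 13 against 53.6 and 59.0.

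Of 537 transcripts lower in KO and tested in both, 383 were also lower at 7 h than at 2 h of TTX and APV, where independent lists would share 160. Of 395 higher in KO, 195 were lower at 7 h against 118 and 33 were higher against 89.1, so changed transcripts of either direction were over-represented among those that fell. Both comparisons use the resting WT libraries. With different WT cultures in each, the median over 16 splits was 6.5 shared lower transcripts against 1.67 for independent lists, and the covariance of log2 fold changes was 0.0257 against 0.123 as observed and 0.132 in simulations without any effect.

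A hypothesis that regions changed in the same direction lie near each other was tested. Within 100 kb of another region changed the same way lay 4.04% of changed regions, against a median of 3.87% in 1000 random draws matched on level (0.673% to 7.41%), so no clustering was seen at this distance.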
